A study of Homo sapiens with 2 samples.

How the data were processed

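The series holds 2 oligonucleotide arrays of 1 group, HEK293 cells, a human embryonic kidney line transformed with adenovirus DNA that grows in continuous culture. Per the labels' protocols, the cells were kept at 37 degrees in medium with 10% serum and taken at 70% confluency, and 4 µg of total RNA per sample was turned into biotin-labelled cRNA for Affymetrix U133 Plus 2.0 arrays. RNA isolation, labelling and hybridisation were done separately for the 2 samples. The labels do not say whether the 2 samples came from separate cultures, so the spread between them may be technical.

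The deposited table gives 1 linear signal intensity per probe set and array, for 54675 probe sets. MAS5 and GCOS are named in the submitters' processing notes, without versions. The mean after trimming 2% at each end was 100.01 on both arrays, as scaling of each array to 1 common target would give; the target is not given in the sources used here. The lowest deposited signal was 0, and 4178 probe sets on array 1 and 3970 on array 2 lay below 1. The detection calls that this software can make were not used here, and the intensities carry no read depth: the 2 arrays limit the precision.

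Probe sets were assigned to genes with the GEO platform annotation, which can be old, and symbols were updated through Entrez identifiers with the RefSeq gene table of GRCh38.p14. Of the probe sets other than the 62 controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none in this annotation. Only probe sets with 1 symbol whose gene was in the RefSeq table were used, which were 41037. They gave a level to 19735 genes, 16516 of them protein-coding. A gene took its probe set with the highest mean level, as fixed before the data were examined, together with the tests, gene lists, naming rule and all alternatives not said to be added later. Because levels of different probe sets also depend on their probes, no ranking of single genes is meant, and groups were compared by medians over many genes. The background call and the correlation of neighbouring genes do use single levels and carry this limit. No genome build is named in the sources used here. The RefSeq table therefore served only for names, chromosomes and the order of genes, and the planned relation of level with gene density and gene length was not run.

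Signals were taken to log2 after raising values below 1 to 1, and signals are given on that floor too. A background limit was set at the 95th percentile of the mean level of 107 probe sets for olfactory receptors (82 genes), a family used mainly in the nose. The limit was 3.82 on the log2 scale, a signal of 14.1, and a gene was called above background when both arrays exceeded it. The median level of each of 32 gene lists was placed among 10000 random lists of protein-coding genes with the same size and the same numbers of probe sets per gene (5 classes). Such a percentile describes these arrays and is no p-value. Of these listed genes, 11 stood in 2 lists, 6 of them keratins that are also in the epithelial list.

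For the transcriptome map, 16508 protein-coding genes were put in order along their chromosomes, and the moving median of 49 consecutive genes was taken in full windows within each chromosome. The limits for high and low windows enclosed the central 95% of the moving medians of 1000 shuffled maps. A domain was a run of at least 10 consecutive windows beyond a limit, and its genes are those at the centres of its windows. It is said to lie around the gene at the centre of its most extreme window, which need not be in the middle of the domain. Spread, window counts, domain counts and correlations of genes 1 to 100 places apart were compared with the 1000 shuffles (one-sided permutation tests). Chromosome medians were compared with 10000 circular shifts of the levels along the gene order (two-sided), which keep the similarity of neighbours, and list members in domains with 1000 shifts (one-sided). P-values within a family were adjusted by Benjamini-Hochberg. Genes are not replicates of the cells, so these tests concern the arrangement of levels in these 2 arrays.

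The scripts were tested on simulated data made from 10 random orders of the 16508 levels. No map without domains had a spread with p under 0.05, with fewer shuffles than in the main analysis. No chromosome was called, but the simulations used too few shifts for a single chromosome to pass after adjustment. Random orders also hold no similarity of neighbours, so the absence of chromosome calls decides nothing about that test. Maps without domains held on average 21.4 runs called as domains. Domain counts are therefore read against shuffles only, and no single domain was tested. Planted domains of 60 genes were recovered in 77.8% of cases at a shift of 2 log2 units and in 36.8% at a shift of 1. Of 40 random lists of 20 genes, 4 fell outside the central 95% with no shift, and 20 did after a shift of 2 log2 units. Alternatives covered the probe set rule, probe sets with shared sequence, each array alone, quantile normalization, window size, limits, run length, shuffling within chromosomes, collapsed tandem families, genes above background, a floor, ranks and all gene types. An adjustment for the number of probe sets per gene and a map without chromosome 19 were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

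Genes named in the text were, for each list, the first 3 measured members in the written or alphabetical order; for the map, the first, extreme and last gene of the 5 most extreme domains in each direction and list members within them; and the 10 genes above background that differed most between the arrays. Other named genes are said to be chosen after their values were seen.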

Results

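Expression in HEK293 cells was measured on 2 arrays, and the study asked how expression levels are laid out in domains along the human chromosomes. With 1 group, the design implies no comparison between treatments. It implies a comparison of the duplicates, of groups of genes with the rest of the genome, and of chromosomal neighbourhoods with one another. The median signal over all probe sets was 16.9 on array 1 and 17.1 on array 2, and the highest signals were 9360 and 8259. Of 16516 protein-coding genes with a level, 11108 (67.3%) were above the background limit on both arrays. Among genes in the map this share rose from 51.9% with 1 probe set to 89.8% with 6 or more. The limit was set on single probe sets while a gene took its highest, so such shares are not plain detection rates.

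Genes above background on both arrays differed little between the duplicates, and the other genes differed more. Over the 11108 genes above background the log2 difference between the arrays had an SD of 0.23, Pearson's r across genes was 0.993, and 97.0% of genes lay within 1.5-fold. Over the 5408 other genes the SD of the difference was 1.42 and r was 0.463. A gene on which the arrays fell on opposite sides of the limit is among these other genes, so the difference itself in part decides this split. Precision rose with level: with expressed genes in 4 equal groups by level, the SD of the difference was 0.097 in the highest group and 0.37 in the lowest. Among expressed genes, 39 differed more than 2-fold, and all 39 were in that lowest group. The largest difference was in SPN, a surface sialoglycoprotein of white blood cells, with signals of 144.0 and 27.0 (5.33-fold). CGAS, the sensor of cytosolic DNA, gave 97.4 and 30.5, and ADAMTS10 gave 47.5 and 16.1; these 3 genes, like LIPE, were read from probe sets whose names mark shared sequence. The other 7 of the 10 genes that differed most were LIPE, SALL4, PRPH, MBLAC1, ACSF3, ABCG4 and AATK, which differed by 2.37-fold to 2.77-fold. With 1 array on each side these differences have no test.

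The bacterial transcripts added at hybridisation were higher on array 1 in 18 of 18 probe sets, by a median of 1.19-fold. The poly-A control probe sets, whose targets can be added before labelling, were not shifted, with 12 of 24 higher on array 1 and a median ratio of 0.9995. The probe sets for 18S ribosomal RNA were 1.56-fold higher on array 1 in the median of 3 probe sets. The ratio of 3′ to 5′ signal was 1.20 ± 0.018 (SD, n = 2) for GAPDH and 2.38 ± 0.20 (SD, n = 2) for ACTB, so both arrays read the 3′ end of ACTB with more signal than its 5′ end.

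The next comparison placed groups of genes against the rest of the genome. Genes of protein synthesis, protein turnover, energy supply and cell division stood at the top. All 27 measured cytosolic ribosomal proteins were above background, with a median level of 12.57 on the log2 scale, and RPS6 had a signal of 6298 ± 303 (SD, n = 2), RPL3 of 5332 ± 123 and RPS3 of 6082 ± 368. Of the 41 genes written in this list, 27 had a level. All 18 translation factors, among them EEF1A1 at 6888 ± 326, EEF2 at 4482 ± 254 and EEF1D at 3048 ± 3.8, had a median of 11.18. All 20 chaperones had a median of 11.50, with HSP90AB1 at 4261 ± 101, HSPD1 at 6218 ± 183 and HSP90AA1 at 5720 ± 358. The 32 nuclear-encoded genes of the respiratory chain had a median of 11.09, with COX4I1 at 3210 ± 84, ATP5F1B at 3268 ± 140 and COX5A at 3822 ± 198. The 27 proteasome genes had a median of 10.78, with PSMA1 at 2641 ± 73, PSMB1 at 3058 ± 134 and PSMC1 at 1870 ± 78. The 18 glycolysis genes, among them GAPDH at 5247 ± 378, ENO1 at 4073 ± 242 and LDHA at 5140 ± 355, had a median of 10.35. The 75 mitochondrial ribosomal proteins had a median of 9.51, with MRPL1 at 365 ± 10, MRPL10 at 618 ± 2.8 and MRPL11 at 485 ± 1.1. Each of these 7 lists had all its measured members above background and a median above all 10000 random lists. Without probe sets of shared sequence, glycolysis stood at percentile 95.5, within the central 95% of random lists.

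Cell cycle genes were among the groups with high levels. All 30 DNA replication genes were above background with a median of 10.01, with PCNA, the sliding clamp of the replication fork, at 2304 ± 183, the helicase subunit MCM2 at 1688 ± 11 and the ribonucleotide reductase subunit RRM2 at 2125 ± 125 (SD, n = 2). All 24 mitosis genes were above background with a median of 9.79, with CDK1 at 2207 ± 461, CCNB1 at 1586 ± 26 and TOP2A at 1049 ± 54. Both medians lay above all random lists. All 17 measured p53 target genes were above background, with CDKN1A at 243 ± 14, MDM2 at 460 ± 34 and GADD45A at 309 ± 5.7. Their median of 7.92 lay at percentile 96.7, within the range of random lists, and at percentile 99.7 when the median of each gene's probe sets was used. The genes of class I antigen presentation were mixed, with 10 of 13 above background and a median of 6.69 at percentile 54.4. B2M, the light chain of class I molecules, had 3265 ± 98 and HLA-B had 1100 ± 70, and the peptide transporter subunit TAP1 had 55.2 ± 2.9.

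**Figure D1:**
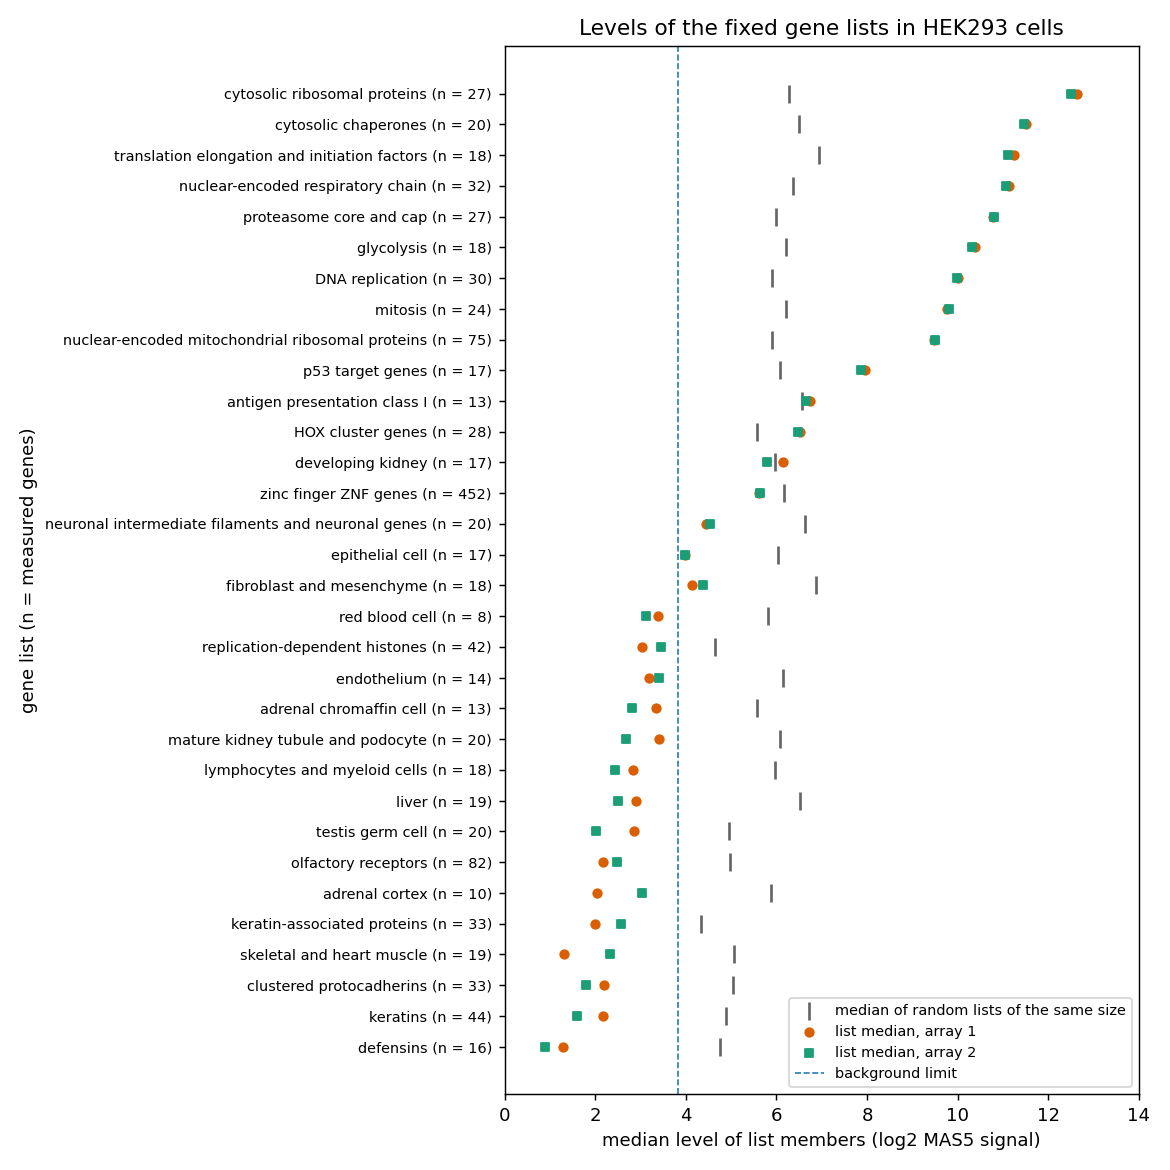
The plot of gene lists gives, on the x axis, the median level of each list in log2 MAS5 signal on array 1 (circles) and array 2 (squares), with the median of random lists of the same size as a grey tick and the background limit of 3.82 as a dashed line; lists are on the y axis with their number of measured genes. Lists of protein synthesis, energy supply and cell division have medians over both arrays between 9.51 and 12.57, and most lists of differentiated tissues lie below the background limit.

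Markers of cell identity were present for parts of several lineages. Of 20 neuronal genes 11 were above background: the neurofilament subunits NEFL at 1113 ± 41 (SD, n = 2) and NEFM at 975 ± 6.0 and the related filament protein INA at 396 ± 13 were among them, while the list's median of 4.29 lay at percentile 1.65. That low place was not kept without probe sets of shared sequence (percentile 11.4) or against unmatched random lists (percentile 6.99). Of 17 developing kidney genes 11 were above background, with the regulators SIX2 at 218 ± 13, WT1 at 123 ± 10 and PAX2 at 36.3 ± 13, and the median lay at percentile 49.9. Of 28 measured HOX genes 25 were above background, with HOXA2 at 34.7 ± 2.3 and HOXB13 at 66.6 ± 13, while HOXB1 at 12.4 ± 0.35 was not, and the median of 6.57 lay at percentile 83.7. Of 17 epithelial genes 9 were above background (percentile 10.6), with CDH1, the epithelial cadherin, at 123 ± 4.2, EPCAM at 126 ± 16 and KRT8 at 193 ± 5.9. Of 18 fibroblast and mesenchyme genes 9 were above background (percentile 0.59, and 5.86 against unmatched lists), with VIM at 2662 ± 26, the neural cadherin CDH2 at 688 ± 17 and COL1A1 at 105 ± 16.

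Genes of most differentiated tissues were at background. Of 20 genes of the mature kidney tubule and podocyte 5 were above it (percentile 0.08): the water channel AQP1 had 23.5 ± 7.6 (SD, n = 2), AQP2 had 15.7 ± 6.3 and was above on 1 array, and NPHS1 had 1.85 ± 0.92. Of 13 chromaffin cell genes 4 were above background, with TH at 3.65 ± 0.64, DBH at 5.60 ± 3.7 and CHGA at 13.6 ± 4.7 below it on at least 1 array. Their median lay at percentile 2.87, at 1.03 against unmatched lists, at 5.415 on array 1 alone and at 1.39 on array 2 alone. Of 10 adrenal cortex genes 2 were above background (percentile 0.27), and STAR, CYP11A1 and NR5A1 were not, at 4.50 ± 4.8, 3.25 ± 3.2 and 11.1 ± 2.3. None of 18 lymphocyte and myeloid genes was above background (percentile 0.03), with PTPRC at 5.65 ± 1.3, CD3D at 3.25 ± 0.50 and CD3E at 8.60 ± 2.3. Of 14 endothelial genes 2 were above (percentile 0.36), and PECAM1 had 12.3 ± 3.3, VWF 11.9 ± 2.8 and CDH5 1.55 ± 0.50. Of 19 liver genes 2 were above (percentile 0.01), and ALB had 6.70 ± 1.4, APOA1 3.60 ± 3.4 and TTR 15.5 ± 5.0. Of 8 red blood cell genes 2 were above (percentile 6.14, and 1.0 with the median of each gene's probe sets), and HBB had 13.8 ± 0.78, HBD 2.70 ± 2.4 and ALAS2 8.30 ± 0.57. Of 19 muscle genes 4 were above (percentile 0.26), and ACTA1 had 13.95 ± 1.8, MYH7 7.40 ± 2.3 and CKM 1.80 ± 0.28. Of 20 testis germ cell genes 2 were above (percentile 0.74), and PRM1 had 2.00 on both arrays, TNP1 7.50 ± 4.8, and DDX4 was at the floor on both. Without probe sets of shared sequence, the endothelial and testis lists moved to percentiles 4.50 and 4.12.

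Several tandem gene families were likewise mostly at background, while most ZNF genes, like the HOX genes, were above it. A signal at background on these arrays does not by itself show that a family's genes are silent. How well the labelling and the probes catch their transcripts was not tested, and probe sets with several gene symbols were left out. Of 44 keratins 5 were above background, among them KRT10 at 671 ± 42 (SD, n = 2), while KRT1 had 11.6 ± 4.9 and KRT12 4.25 ± 0.78. None of 33 keratin-associated proteins was above it, with KRTAP1-1 at 8.70 ± 6.2, KRTAP1-3 at 6.65 ± 4.2 and KRTAP1-5 at 1.80 ± 0.28, and none of 16 defensins, with DEFA4 at 3.45 ± 1.3, DEFA5 at 2.95 ± 2.8 and DEFA6 at 3.40 ± 2.1. Of 33 clustered protocadherins 3 were above it, among them PCDHA5 at 19.8 ± 1.1, while PCDHA10 had 6.40 ± 6.5 and PCDHA2 2.80 ± 2.5. These 4 families had medians at or below percentile 0.22 of their random lists. The olfactory receptors, which set the limit, had 5 of 82 genes above it; OR10A3, OR10A4 and OR10A5 had 1.5 ± 0.71, 3.25 ± 3.2 and 2.95 ± 2.6, and the median lay at percentile 0.0. Of 42 replication-dependent histones 12 were above background, with H1-2 at 102 ± 16 while H1-1 had 5.70 ± 3.7 and H1-3 10.8 ± 4.9, and the median lay at percentile 1.74 (0.935 on array 1 alone, 4.92 on array 2 alone and 2.96 without probe sets of shared sequence). Of 452 ZNF zinc finger genes 344 were above background, with ZNF10 at 34.0 ± 0.49, ZNF100 at 27.7 ± 0.92 and ZNF101 at 81.0 ± 1.2. Their median of 5.62 lay at percentile 0.96, but at percentile 18.3 when the median of each gene's probe sets was used and 27.985 without probe sets of shared sequence. Over the 32 lists, 9 had medians above and 16 below the central 95% of their random lists.

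The transcriptome map asked whether genes of high or low level lie together along the chromosomes. They did, beyond chance: moving medians of 49 genes ranged from 1.95 to 8.52 on the log2 scale around a median gene level of 6.19, and their SD was 1.18. Shuffled maps had a mean SD of 0.72 and at most 0.79 (permutation p = 0.001, the smallest that 1000 shuffles can give). Of 15388 windows, 1827 (11.9%) lay above the upper limit of 7.38 and 1860 (12.1%) below the lower limit of 4.51, against means of 384.5 and 384.1 in shuffled maps (permutation p = 0.001 each). These windows formed 47 high domains with 1554 genes and 44 low domains with 1643 genes, against at most 25 and 24 domains in any shuffle (permutation p = 0.001 each). The map was alike on both arrays: the SD of the difference between moving medians was 0.19, and of the genes in domains on array 1 alone, 87.7% for high and 86.5% for low domains were in such domains on array 2 alone. As follows from how domains were defined, the share of genes above background differed: in high domains it was 79.5%, in low domains 43.6%, and outside domains 68.8%. The mean number of probe sets per gene differed too, at 2.45 in high domains, 1.90 in low domains and 2.23 outside. Genes with 1 probe set made up 33.3%, 53.1% and 40.6%. Levels rose with probe set number, so part of the contrast between domains may rest on it.

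**Figure D2:**
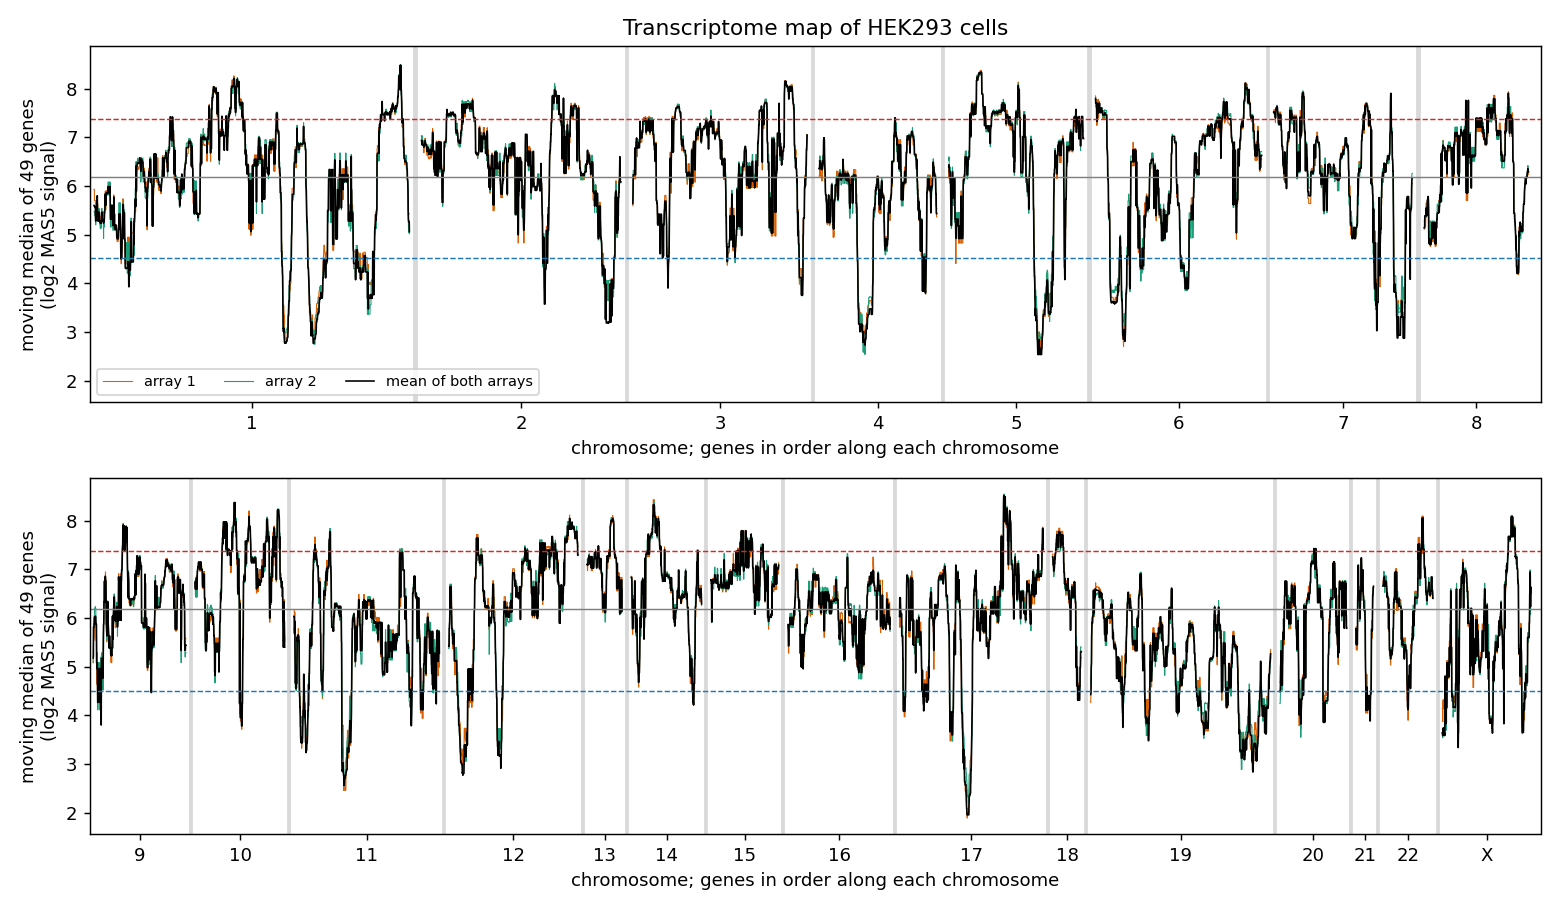
The transcriptome map gives the moving median of 49 genes (y axis, log2 MAS5 signal) against gene order along each chromosome (x axis) for array 1, array 2 and their mean. Dashed lines mark the upper limit of 7.38 and the lower limit of 4.51 and the grey line the median gene level of 6.19; the deepest minimum, 1.95 on chromosome 17, lies over genes of keratins and keratin-associated proteins.

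The domains below are ranked by their most extreme moving median and none has a test of its own, since maps with no domain also held runs called as domains, 21.4 on average. The highest, on chromosome 17, ran over 32 genes, 23 of them above background, from COIL, the marker protein of Cajal bodies, to DHX40, and reached a moving median of 8.52 (8.54 on array 1 and 8.55 on array 2). COIL had a signal of 774 ± 5.7 (SD, n = 2), DHX40 of 867 ± 23 and the mitochondrial ribosomal protein MRPS23 of 1230 ± 65, while CCDC182, on which its highest window was centred, and the olfactory receptors OR4D1 and OR4D2 within it had 11.3 ± 4.0, 7.65 ± 9.4 and 9.20 ± 3.3. The moving median around CCDC182 lay 0.42 log2 units below the median gene when genes with several probe sets were left out, and it was within the limits with windows of 19 or 39 genes (0.46 and 0.40 above) or with all gene types (1.26 above). The next domain, on chromosome 1, ran over 58 genes (46 above background) from LEFTY1 to COA6 around DISC1, with a moving median of 8.48; COA6 had 691 ± 57, the mitochondrial ribosomal protein MRPL55 308 ± 7.5, the histone H2AC25 200 ± 3.5 and ZNF678 160 ± 6.6, while LEFTY1 had 9.30 ± 4.1 and DISC1 9.30 ± 1.8. On chromosome 10, 34 genes (28 above background) from ASCC1 to COMTD1 around MYOZ1 reached 8.37, with ASCC1 at 340 ± 9.5, MRPS16 at 883 ± 102 and COMTD1 at 150 ± 17, while MYOZ1 had 12.75 ± 0.21 and was not above background. On chromosome 5, 69 genes (53 above background) from SNX18 to TMEM171 around PIK3R1 reached 8.34, with SNX18 at 452 ± 6.8, the mitotic cyclin CCNB1 at 1586 ± 26, the tight junction gene OCLN at 632 ± 0.35, MRPS27 at 607 ± 119, PIK3R1 at 76.15 ± 1.1 and TMEM171 at 22.6 ± 3.8, while DDX4 within it was at the floor and ZNF366 had 4.40 ± 4.8. On chromosome 14, 73 genes (67 above background) from FKBP3 to RTN1 around TMX1 reached 8.33, with FKBP3 at 1840 ± 96, TMX1 at 1513 ± 30, RTN1 at 52.7 ± 4.5 and the proteasome genes PSMC6 at 1721 ± 34 and PSMA3 at 2293 ± 45. The window around MYOZ1 was within the limits among genes with 1 probe set (0.75 above the median gene) and without probe sets of shared sequence (1.17), and that around TMX1 with windows of 19 genes (1.49).

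The 5 deepest low domains all had extreme moving medians below the background limit of 3.82. Levels of single genes repeated poorly between the arrays there, so the order of these domains by depth is uncertain. The deepest low domain lay on chromosome 17 and held 71 genes from PSMD3 to ACLY around KRTAP4-6, with a moving median of 1.95 (1.89 and 2.46 on the 2 arrays). It held 23 keratin-associated proteins, none above background, with KRTAP4-6 at 5.10 ± 4.7, and 23 keratins, of which 2 were. The domain held 20 genes above background in all, these 2 keratins included, among them the proteasome gene PSMD3 at 823 ± 17 (SD, n = 2), CDC6, which loads the replication helicase, at 591 ± 27, the topoisomerase TOP2A at 1049 ± 54 and ACLY, which makes acetyl-CoA in the cytosol, at 1967 ± 13. The second, on chromosome 5, held 93 genes (36 above background) from CD14 to PDGFRB around PCDHGA1, with a moving median of 2.53. All 33 measured clustered protocadherins were in it, 3 of them above background and PCDHGA1, at 10.75 ± 7.4, on 1 array only; the respiratory chain gene NDUFA2 had 1062 ± 1.3, and CD14, CSF1R and PDGFRB had 3.60 ± 3.7, 7.40 ± 6.9 and 6.50 ± 3.8. With tandem families collapsed to 1 gene per neighbourhood the moving median around PCDHGA1 fell short of the lower limit, at -0.52 log2 units from the median gene.

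The other 3 of the 5 deepest low domains held few members of the fixed lists. On chromosome 11, 63 genes (27 above background) from SSRP1 to CPSF7 around ZDHHC5 reached 2.56, with SSRP1 at 1529 ± 3.0 (SD, n = 2), ZDHHC5 at 385 ± 35, CPSF7 at 330 ± 22 and MRPL16 at 732 ± 29; the B cell gene MS4A1 had 6.60 ± 1.6. On chromosome 4, 80 genes (28 above background) from REST to STBD1 around RUFY3 reached 2.73, with ALB at 6.70 ± 1.4 and STBD1 at 2.70 ± 0.57 but REST, a repressor of neuronal genes, at 148 ± 10 and RUFY3 at 172 ± 22. On chromosome 1, 100 genes (39 above background) from MRPL24 to MGST3 around OR10J1 reached 2.76, with OR10J1 at 7.80 ± 2.7, APOA2 at 6.40 ± 7.6, CASQ1 at 1.45 ± 0.35 and FCER1G at 9.15 ± 5.6, and with MRPL24 at 452 ± 0.28, SDHC at 1003 ± 9.5 and MGST3 at 915 ± 46. Among genes above background alone, the windows around ZDHHC5 and RUFY3 lay above the median gene, by 0.49 and 0.10 log2 units, and with windows of 19 genes they were within the limits, at -1.52 and -1.13. The window around OR10J1 was within the limits among genes with 1 probe set, at -1.33.

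Members of some families lay in low domains more often than in shifted maps, but no list passed this test after adjustment. The members' own low levels helped to make these domains, so their presence there in part restates their low levels. All 44 keratins lay in low domains (permutation p = 0.007), as did 31 of 77 olfactory receptors (permutation p = 0.007), all 33 protocadherins (permutation p = 0.039), 30 of 42 histones (permutation p = 0.05) and 88 of 403 ZNF genes (permutation p = 0.024). Of 32 keratin-associated proteins 23 did (permutation p = 0.074). Epithelial genes, with 7 of 16 in low domains, 6 of them keratins, had permutation p = 0.008, and lymphocyte and myeloid genes, with 6 of 17, had permutation p = 0.01. In high domains, 8 of 31 respiratory chain genes were found against 3.14 in shifted maps (permutation p = 0.007). None of the 60 tests over 30 lists and both directions passed 0.05 after adjustment, the lowest adjusted permutation p being 0.12, and 8 had an unadjusted permutation p of 0.05 or less. Ribosomal proteins, with 2 of 25 in high domains, lay there about as often as in shifted maps, with 2.46.

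Levels of neighbouring genes were correlated, most at the shortest distance. Pearson's r across gene pairs was 0.18 for adjacent genes, 0.11 at 2 places, 0.053 at 5, 0.042 at 10, 0.031 at 20, 0.018 at 50 and 0.015 at 100. The first 5 exceeded every shuffle (adjusted permutation p = 0.0014), and those at 50 and 100 places had adjusted permutation p = 0.019 and 0.036 over 7 distances. The shuffles ran over all chromosomes, so differences between whole chromosomes can add to r at any distance. The small values at 50 and 100 places therefore do not show similarity over that range within chromosomes. Among genes above background alone the correlation of adjacent genes was 0.064, and with tandem families collapsed it was 0.11 (permutation p = 0.001 each).

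**Figure D3:**
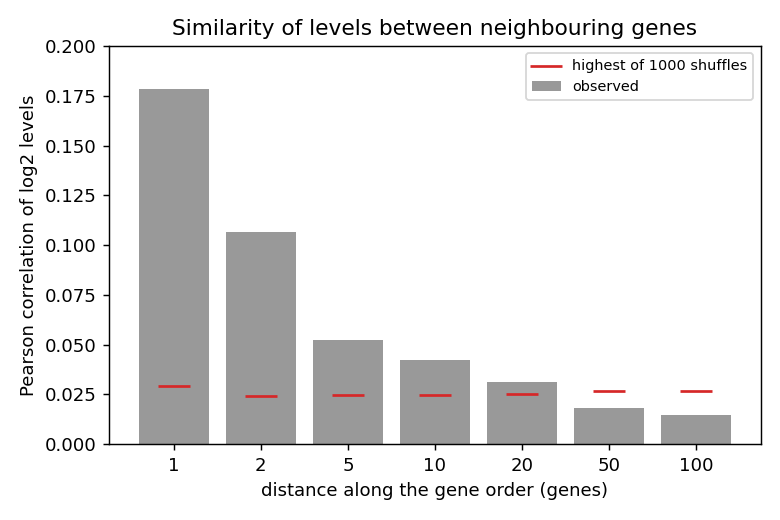
The plot of neighbour similarity gives Pearson's r of log2 levels (y axis, bars from 0) for pairs of genes 1 to 100 places apart on a chromosome (x axis), with the highest value of 1000 shuffles as a red mark. The correlation drops from 0.18 for adjacent genes to 0.015 at 100 places.

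Whole chromosomes differed less clearly. No chromosome's median passed 0.05 after adjustment over 23 chromosomes, and 1 had an unadjusted permutation p under 0.05. That was chromosome 19, rich in ZNF genes, whose 1221 genes had a median of 5.04 ± 0.034 (SD of the medians of 2 arrays), 1.16 log2 units below all genes (permutation p = 0.026, adjusted permutation p = 0.59). It was named after its value was seen. Among genes above background its 748 genes lay 1.04 log2 units below all such genes (adjusted permutation p = 0.014), but these genes were selected by the level that is compared, so this call decides nothing about the chromosome as a whole. Among genes with exactly 1 probe set the difference was -0.22. It was -0.66 with levels adjusted for the number of probe sets and -0.72 with the median of each gene's probe sets. Over the other alternatives the adjusted permutation p lay between 0.41 and 0.93. Low domains covered 29.2% of its windows in 7 domains, and none of the 47 high domains lay on it. High domains covered the largest shares of chromosomes 10 (29.3%, 7 domains), 18 (27.1%, 1 domain) and 5 (26.0%, 4 domains).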

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

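These counts, of probe sets that the comparisons left out, were not fixed in advance. Of 11721 probe sets with no gene symbol in the annotation used here, 3675 (31.4%) were above the background limit on both arrays, 911 had a signal over 100 on both, and 107 had one over 1000 on both. Of 1801 probe sets with several gene symbols, 1036 (57.5%) were above the limit. For comparison, 5 of 107 olfactory receptor probe sets (4.67%), which set the limit, and 54.3% of probe sets with 1 gene were above it on both arrays. No group had 4 or more arrays and no contrast was measured in 2 groups, so neither single outlying arrays nor differences between groups were looked for.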

How the results depend on the processing

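The adjustment for probe set number and the map without chromosome 19 were chosen after seeing the data. The spread of moving medians, the neighbour correlation and the window and domain counts exceeded every shuffle under every alternative run, but permutation p = 0.001 is the floor of 1000 shuffles and does not measure how far they held. Among genes above background the SD of moving medians fell from 1.18 to 0.56 (shuffled mean from 0.72 to 0.36, at most 0.40) and the correlation of adjacent genes from 0.18 to 0.064. The SD between duplicates was 0.83 over all genes and 0.23 among genes above background. With only genes that have 1 probe set there were 481 windows above and 583 below the limits and 18 high and 15 low domains; with only genes above background 1044, 971, 24 and 21; with stricter limits 672, 1094, 21 and 25. Runs of at least 25 windows gave 27 high and 29 low domains, windows of 19 genes gave 1000 windows above and 31 high domains, collapsed families gave 1031 windows below and 27 low domains, and shuffling within chromosomes gave 1119 windows above. Levels adjusted for the number of probe sets gave 1159 windows above and 28 high domains. Fewer genes, windows or a stricter limit account for part of these drops by construction; otherwise the cause was not tested. Each array alone gave 1787 to 1827 windows above, 1817 to 1828 below, 42 to 47 high and 41 to 45 low domains, and an SD of 1.14. Among genes above background chromosome 19 passed the adjusted threshold, the only chromosome to do so (1 lower), but these genes were selected by the level that is compared. The moving median around CCDC182 changed sign among genes with 1 probe set (-0.42), as did those around ZDHHC5 (0.49) and RUFY3 (0.10) among genes above background; the cause was not tested. The number of genes in domains under an alternative caps the share of reported domain genes that could stay. Domains under stricter limits lie inside the reported ones by construction, so their full overlap is no support. All alternatives reuse the same 2 arrays, so the counts if independent are a reference and not a test. Of the genes in high domains under an alternative, those also in the reported high domains were 388 of 555 with windows of 19 genes (24.97% of the reported genes in that map), 118 of 379 among genes with 1 probe set (25.3%), 496 of 496 with stricter limits (31.9%), 552 of 882 with the adjustment for probe set number (35.5%), 464 of 837 among genes above background (37.8%) and 650 of 1112 with the median of each gene's probe sets (41.8%), against 54.9, 31.1, 50.1, 89.1, 102.7 and 112.3 genes if independent. For low domains these were 762 of 1109 (46.4%), 362 of 496 (43.1%), 963 of 963 (58.6%), 1082 of 1350 (65.9%), 190 of 849 (26.8%) and 1202 of 1494 (73.2%), against 118.0, 73.3, 102.8, 144.1, 60.3 and 159.5. Of 192 single list results under alternatives, 178 kept their side of the limits, 10 lost and 4 gained a call, and none reversed. The relation with gene density and gene length was not run because no build is named in the sources used here. No paired analysis was possible because there is only 1 group. Precision is limited by the 2 arrays and, for genes not above background on both, by signals that repeated poorly between them (r = 0.463).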

Other observations

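The family counts below, and the tests of chromosome 19 among genes with 2 probe sets and among genes above background with 1 probe set, and the adjustment of levels for probe set number, were chosen only after the results were seen. Beyond the fixed lists, 231 families of protein-coding genes with a shared symbol stem and at least 10 measured members were examined. In 25 of them every member was above background. These included the RNA splicing factors of the SRSF family (10 genes, median 10.53 ± 0.015 on the log2 scale, SD of the medians of 2 arrays), the LSM proteins of small nuclear RNA particles (13 genes, 9.69 ± 0.084), RNA polymerase subunits of the POLR family (30 genes, 8.90 ± 0.040), the exosome subunits EXOSC (10 genes, 8.56 ± 0.013), the CNOT deadenylase complex (11 genes, 8.76 ± 0.022), the centrosomal CEP proteins (35 genes, 7.40 ± 0.087) and the ciliary transport proteins IFT (18 genes, 7.73 ± 0.043). All but the last 2 of these lay above the central 95% of random lists. In 9 families no member was above background, among them the chemokines CCL (20 genes, 1.77 ± 0.15), the inflammasome sensors NLRP (15 genes, 1.68 ± 1.1), the type I interferons IFNA (11 genes, 1.48 ± 0.85) and the natural killer receptors KIR (13 genes, 0.85 ± 0.26). Of the measured HOX genes, 9 of 10 in the HOXB cluster, 8 of 9 in HOXC and 7 of 8 in HOXD were above background, with medians of 6.65, 6.58 and 6.44.

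For the grouping of levels along the gene order, no explanation that was tested accounts, by itself, for the whole. Genes with more probe sets had higher levels, from a median of 4.28 with 1 probe set to 7.65 with 6 or more, but in the map of genes with exactly 1 the SD of moving medians was 1.16 against at most 0.99 in shuffles. With tandem families, whose probes may also cross-hybridise, collapsed it was 0.94 against at most 0.72, and against shuffles within chromosomes it was 1.18 against at most 0.89. Families were collapsed by a shared symbol stem within 10 places. Longer families kept more than 1 gene, and neighbouring paralogs with other stems stayed in. Tandem families are therefore argued against as the whole only as so defined. Blocks of silent genes are not the whole either, since adjacent genes above background still correlated at 0.064 against at most 0.035 in shuffles, though this was 0.18 over all genes. Those shuffles ran over all chromosomes and tandem families were kept, so both can contribute to the 0.064. The series has 1 group, so no biological explanation was tested by comparing groups of samples; these tests concern the arrangement of levels within 2 arrays. GC content, probe affinity and any other explanation that these 2 expression arrays do not measure stay open.

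The low median of chromosome 19 may rest in part on how many probe sets its genes have, a mean of 1.88 against 2.24 elsewhere. Adjusting levels for probe set number moved its difference from all genes from -1.16 to -0.66. The median of each gene's probe sets moved that difference to -0.72. Among genes with 1 probe set the difference of its median from the rest was -0.25 (95% bootstrap interval -0.62 to 0.12). That lay within the 0.3 log2 units fixed beforehand as the sign of this cause, though the interval reached further. Over the whole map genes with 1 probe set had a median level of 4.28, and 51.9% were above background. Their median thus lay near the background limit, where a difference among expressed genes can be hidden. Although the rule was met, the value of -0.25 therefore does not decide how much probe set number accounts for. As the whole cause, probe set number is argued against for genes with 2 probe sets (-1.22, interval -1.52 to -0.79), within the limits of these intervals given below. That test was added after the results were seen. For genes above background with 1 probe set the difference was -1.03 (interval -1.39 to -0.79). These were selected by the level that is compared, so this value concerns expressed genes only and decides nothing for the chromosome as a whole. ZNF genes as the whole cause are argued against too, as the difference was -1.26 (interval -1.63 to -0.85) without them. All these intervals treat genes as independent, though levels of neighbouring genes correlate, so they may be too narrow. The low median itself did not pass the test by circular shifts (adjusted permutation p = 0.59), so the pattern weighed here is not established. Base composition of its transcripts remains open and was not tested.

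A hypothesis was that low domains are places of silent genes whose expressed members have usual levels. Genes above background in low domains differed from those outside domains by -0.36 log2 units (95% bootstrap interval -0.58 to -0.11), between the 0.3 that the hypothesis allowed and the 0.6 that would have excluded it, so it stays undecided. The domains were defined by these same levels, so the value is not independent of the definition. The interval also treats genes as independent, though levels of neighbouring genes correlate, and may be too narrow. In high domains genes above background lay 0.72 log2 units higher than those outside (interval 0.59 to 0.87), with the same caveats.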
